A study of Mus musculus with 20 samples.

How the data were processed

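Liver tissue of 20 samples was analysed, in 5 groups of 4 that the sample titles define by diet, exercise arm and, on the high-fat diet, tumour or non-tumour piece. Per the labels' protocols, total RNA was taken from frozen liver with RNAiso Plus, and libraries were made with a stranded mRNA kit, which selects polyadenylated transcripts. Per the submitters' processing notes, Trim Galore 0.6.10, STAR 2.7.11a and featureCounts of Subread 2.0.5 were used with the genome build GRCm39. The deposited values are raw read counts per gene, made with featureCounts 2.0.5 over exons grouped by gene with a GENCODE annotation, per the file headers. The strand setting was 2 (reverse-stranded), per the file headers, so counts of a gene and of an overlapping antisense gene were told apart. The headers name no option for read pairs, for multi-mapping reads or for reads over several genes, so reads that match near-identical copies or genes overlapping on 1 strand were left uncounted and such genes are under-counted. Trimming, alignment and duplicate settings, read length and read layout are not given in the sources used here.

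All computing started from the deposited counts. The files hold 55359 gene identifiers, of which 52083 had a symbol in the gene name table used; 135 that share a symbol were named by identifier. Symbols are those of that table, in which Bmal1 is Arntl. Coordinates are those of the files, on GRCm39. Genes were kept by filterByExpr over the 5 groups (minimum count 10, minimum total 15), which left 14428. Library sizes were scaled by TMM. For each gene the quasi-likelihood negative binomial model of edgeR 4.0.16 (robust option, in R 4.3.3 with limma 3.58.1) was fitted to the 5 group means over all 20 libraries, with 15 residual degrees of freedom and no further covariate. Contrasts were high-fat against normal diet in non-exercised non-tumour liver, exercised against non-exercised mice in non-tumour and in tumour pieces, tumour against non-tumour pieces in each arm, and the interaction of exercise and tumour. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the root of the F statistic, and all tests are two-sided. CPM values use TMM-scaled library sizes, and log2 CPM carries a prior count of 2.

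In the library with fewest counts a gene at 1 CPM holds 16.5 counts, so that counting error is large for genes near that level, and spread between libraries dominates for abundant genes. Libraries of a group were compared by correlation and by a chi-square test of their counts. The lowest chi-square per gene over any pair within a group was 10, where sampling noise gives about 1, so none was treated as a library deposited more than once, which does not show that they are separate mice. Total counts, the share of the most abundant genes and principal components were looked at for batches; the labels give no library or sequencing batch.

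The procedure was tested on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed by known folds. For exercise in non-tumour liver (14242 simulated genes tested) it recovered 28.4% of 67 genes changed 1.5-fold, 67.2% of 67 changed 2-fold and 97% of 66 changed 4-fold, and 2.3% of its 131 calls were false. For the diet (14229 genes) it recovered 32.8%, 68.7% and 97%, and 6.4% of its 141 calls were false, above the 5% aimed at.

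The design of each test, the rule for naming genes, 48 gene lists of pathways, cell type markers and RNA quality, and most alternatives were fixed before the data were examined. In each comparison the text names the 10 genes of the series title (E2f1, Myc, Cry1, Cry2, Per1, Per2, Per3, Nr1d1, Dbp, Bmal1). It also draws on the 6 highest and 6 lowest fold changes among genes that passed with a mean of at least 1 CPM and a proper symbol; where none passed, the 5 smallest p were taken. Of each list up to 4 members with the smallest p among those called were eligible, or, with none called, the 2 of the highest mean CPM. Some genes that this rule names are not reported here. Where a family of near-identical copies was involved, the value is given as uncertain. A list was described only if at least 2 members were called, if its camera adjusted p was under 0.05, or if it concerned the clock, E2F, G2 and M phase, Myc, another cell type or RNA quality. Some lists with called members but no camera call are not reported here. Lists were tested with camera (limma) at the preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the 48 lists per comparison. Members were also adjusted over the list alone. The list members Ddit3, Aldoa and Ahsp had no identifier under those symbols and were left out.

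Alternatives were RLE and upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom with the mouse as a random block, no filter on low counts, a filter of 1 CPM in 4 libraries, a fit of only the groups compared, a fixed block (the mouse for tumour comparisons and the interaction, the number for the others), and leaving out each library in turn. Leaving out pieces that stood apart on the first principal component (both tumour pieces numbered 3, and exercised non-tumour pieces numbered 1 and 2), leaving out libraries in the list tests, and the block together with an estimated correlation were chosen after seeing the data. In an arm, tumour and non-tumour pieces with 1 number in the titles were read as pieces of 1 mouse. Deviations from the group means correlated in these pairs with r of -0.08, 0.1, 0.21 and 0.05 in non-exercised and 0.08, 0.44, 0.37 and 0.31 in exercised mice. The block was fixed as an alternative before the data were examined, and calls it changed are given beside the tumour results. Exact permutation tests over the 70 assignments of 8 libraries to groups of 4 were used for single scores, which are means of the members' log2 CPM after subtracting each gene's mean over all libraries. For each comparison of 4 libraries against 4 the fit was repeated for all 35 splits, and for the interaction for 100 drawn regroupings. For diet and exercise effects that share libraries, 20 sets of unchanged groups were simulated and the shared libraries were divided in 6 ways. Proteins, body weights and tumour numbers were not analysed here.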

Results

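Polyadenylated RNA was sequenced from 20 frozen liver samples of male wild-type mice whose strain the labels spell C56BL/6. Pups were painted on postnatal day 4 to 5 with 50 µL of 0.5% 7,12-dimethylbenz(a)anthracene, a carcinogen known as DMBA, and livers were collected at 35 weeks of age. The samples form 5 groups of 4 libraries: livers of non-exercised mice on a normal diet (12 kcal% fat), and non-tumour pieces and tumour pieces of mice on a high-fat diet (60 kcal% fat), each taken from non-exercised and from exercised mice. Exercise was treadmill running: after 5 weeks of training that began at 10 m/min, mice ran at 18 m/min for 20 min a day on 5 days a week for the last 10 weeks. The high-fat arms were killed on the same day, within 2 h of the final run, and the labels give neither the clock time nor the sampling day of the mice on the normal diet. The series title names its subject as exercise, degradation of E2F1 and c-Myc, and circadian genes; transcripts but not proteins were measured here. The titles number mice 1 to 4 in each group, and tumour and non-tumour pieces of an arm with 1 number were read as pieces of 1 mouse; p-values measure the spread between these samples.

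Total counts per library were 16626648 to 18826889 on the normal diet, 16471378 to 18142796 in non-exercised non-tumour liver and 18171377 to 19824518 in non-exercised tumours. They were 16809124 to 19513821 in exercised non-tumour liver and 19240957 to 20271948 in exercised tumours. Correlations of log2 CPM between libraries of a group lay between 0.934 (non-exercised tumours) and 0.99 (normal diet), and no pair of libraries was alike within sampling noise. Albumin (Alb), the main plasma protein made by hepatocytes, took 4.06 to 7.36% of the counts of liver libraries other than tumours and 9.05 to 15.9% of those of tumours. Mitochondrially encoded genes took 4.54 to 5.99% and 2.56 to 4.5% of the counts in these sets of libraries. The first principal component held 58.3% of the variance and ordered the libraries from normal-diet liver to tumours. Gene values are given as log2 fold change ± SE from edgeR, with 4 libraries in each group compared, and an adjusted p is the Benjamini-Hochberg value over the 14428 genes tested. Gene lists were tested with camera at its preset correlation, and p of lists are adjusted over the 48 lists. With an estimated correlation, the calls that held were those of the circadian clock list in both exercise comparisons, and no other.

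**Figure D1:**
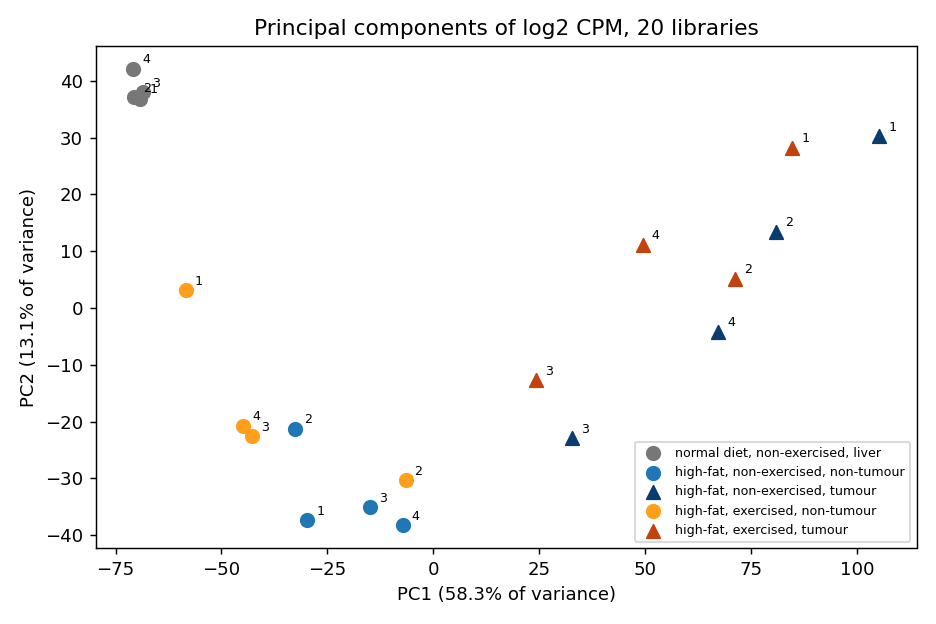
Scores of the 20 libraries on principal components 1 (58.3% of the variance) and 2 (13.1%) of log2 CPM, 1 point per library, with the replicate number beside it; circles are liver or non-tumour pieces and triangles are tumour pieces. The 4 normal-diet libraries lie between -70.9 and -68.4 on component 1 and the 8 tumour pieces between 24.3 and 105.

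The high-fat diet was compared with the normal diet in liver without tumour, both in non-exercised mice. Transcripts of lipid storage rose: Cidec (3.09 ± 0.30) and Cidea (6.64 ± 0.93), which coat lipid droplets, Cd36 (1.84 ± 0.26), a fatty acid receptor, and Apoa4 (4.54 ± 0.52), an apolipoprotein of triglyceride secretion. Transcripts of male-type liver fell, among them the steroid dehydrogenase Hsd3b5 (-8.89 ± 1.79) and the selenium-binding protein Selenbp2 (-5.47 ± 0.92). Myc, a growth-promoting transcription factor, fell (-2.61 ± 0.47, adjusted p = 0.00103, 4 of 4 libraries below all of the normal diet). E2f1, a transcription factor of S phase entry, did not pass (0.33 ± 0.14, adjusted p = 0.101). In all, 3740 of 14428 genes passed, 2025 higher and 1715 lower, and 1100 and 311 of them by at least 2-fold. Of calls, 54.1% were higher, against 68.8% with upper-quartile factors.

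Lipid synthesis genes moved with the storage genes on the high-fat diet. Of 15 measured members of the lipid droplet and PPARG list, 10 rose and 0 fell, and 12 rose and 1 fell when adjusted over the list alone (median 1.58, camera p = 1.1e-08, estimated-correlation p = 0.158). Of 20 fatty acid synthesis genes, 10 rose and 1 fell, the same counts as when adjusted over the list alone (camera p = 4.24e-05, estimated-correlation p = 0.503). They included the lipid droplet lipase Pnpla3 (4.07 ± 0.48) and the desaturase Fads2 (1.34 ± 0.20). Among 23 cholesterol synthesis genes 5 rose, also 5 when adjusted over the list alone, with Mvd, a mevalonate pathway enzyme, at 1.66 ± 0.33 (camera p = 0.00966, estimated-correlation p = 0.678). Irs2 (-2.22 ± 0.37), an adaptor of insulin signalling, and the insulin-repressed Igfbp1 (-2.56 ± 0.63) fell.

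Part of the genes of hepatocyte function fell on the high-fat diet. Of 18 hepatocyte identity genes 6 fell and 0 rose, as when adjusted over the list alone (camera p = 0.00216, estimated-correlation p = 0.416), including Cps1 (-1.31 ± 0.21), the entry enzyme of the urea cycle, and Hnf4a (-0.65 ± 0.11), a master regulator of hepatocyte genes. Of 17 xenobiotic metabolism genes 2 rose and 6 fell (2 and 9 adjusted over the list alone, camera p = 0.00241, estimated-correlation p = 0.416). Ces2a (-2.44 ± 0.27), a carboxylesterase, and the drug-metabolising cytochromes Cyp2b10 (-6.21 ± 1.08) and Cyp3a11 (-1.76 ± 0.39) fell. Of 16 male-biased genes 9 fell and 0 rose, 11 and 0 when adjusted over the list alone (camera p = 2.39e-06, estimated-correlation p = 0.531). Of 10 measured female-biased genes 6 rose and 1 fell, the same as over the list alone (camera p = 0.00238, estimated-correlation p = 0.416). Ugt2b38 (-5.97 ± 1.08), which fell, and Cyp2b9 (6.28 ± 0.86), which rose, belong to families of near-identical copies and are uncertain.

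Cell cycle, stress and tumour marker lists also moved. Of 25 G2 and M phase genes 20 rose and 0 fell (21 and 0 adjusted over the list alone, median 2.37, camera p = 1.78e-11, estimated-correlation p = 0.432). Levels were low: Mki67, a proliferation marker, went from 1.03 ± 0.0624 to 8.25 ± 4.44 CPM (mean ± SD, n = 4; 2.99 ± 0.55). The topoisomerase Top2a (2.56 ± 0.45) and Ube2c (2.62 ± 0.42), a ubiquitin-conjugating enzyme of mitotic exit, rose too. Of 32 E2F target and S phase genes 8 rose and 2 fell, as over the list alone (camera p = 0.0124, estimated-correlation p = 0.604). Of 26 Myc targets 11 fell and 0 rose (14 and 1 adjusted over the list alone, camera p = 2.1e-05, estimated-correlation p = 0.416). Of 18 p53 targets 8 rose and 0 fell, also when adjusted over the list alone (camera p = 0.00275, estimated-correlation p = 0.604). Of 17 NRF2 targets 9 rose and 1 fell, likewise over the list alone (camera p = 0.0072, estimated-correlation p = 0.531). Of 29 measured liver tumour markers 10 rose and 0 fell (12 and 0 adjusted over the list alone, camera p = 8.87e-07, estimated-correlation p = 0.416), among them the proteoglycan Gpc1 (2.27 ± 0.14) and the annexin Anxa2 (3.05 ± 0.33).

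Markers of other cell types shifted in the same libraries. Of 14 markers of lipid-associated and monocyte-derived macrophages 10 rose and 0 fell (11 and 0 adjusted over the list alone, median 2.22, camera p = 2.91e-07, estimated-correlation p = 0.416). They included galectin Lgals3 (2.37 ± 0.37), the chemokine receptor Ccr2 (2.87 ± 0.45) and the integrin Itgax (2.86 ± 0.50). Of 13 resident macrophage markers 7 rose and 0 fell, as over the list alone (camera p = 0.0124, estimated-correlation p = 0.604), with Cd68 at 1.48 ± 0.30. Of 20 interferon response genes 17 rose and 0 fell (18 and 0 adjusted over the list alone, camera p = 1.24e-11, estimated-correlation p = 0.158). Of 9 MHC class II genes 6 rose (7 over the list alone, camera p = 0.00984, estimated-correlation p = 0.604), with their transactivator Ciita at 1.88 ± 0.40. Of 22 stellate cell and fibrosis genes 10 rose and 0 fell (12 and 0 adjusted over the list alone, camera p = 9.72e-06, estimated-correlation p = 0.595). Sinusoidal endothelial markers went the other way: 4 of 12 fell, also over the list alone (camera p = 0.00228, estimated-correlation p = 0.601). Of 6 erythroid markers 5 rose and 0 fell (5 rose and 1 fell adjusted over the list alone, camera p = 0.0335, estimated-correlation p = 0.604), with the haemoglobin genes Hba-a1 (1.48 ± 0.37) and Hbb-bs (1.64 ± 0.42) uncertain because copies share reads. Of 7 mitochondrially encoded genes 1 fell, mt-Nd1 (-0.51 ± 0.17, adjusted p = 0.0373), and 0 when adjusted over the list alone (camera p = 0.0454, estimated-correlation p = 0.604). The mt-Nd1 call was lost with upper-quartile factors (0.0762) and without any of normal-diet libraries 1, 3 and 4 or high-fat libraries 2, 3 and 4 (adjusted p 0.0509 to 0.105).

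Clock transcripts differed between the diets in both directions. Of 19 circadian clock genes 4 rose and 5 fell (5 and 5 adjusted over the list alone), and the list had no call (camera p = 0.923, estimated-correlation p = 0.935). The output regulator Dbp (3.14 ± 0.62), the repressors Nr1d1 (1.39 ± 0.26) and Nr1d2 (1.13 ± 0.20) and Per3 (1.54 ± 0.34) rose, and Nfil3 (-1.29 ± 0.22), which represses Dbp targets, fell. Cry1 fell (-1.12 ± 0.34, adjusted p = 0.0233), a call lost without normal-diet library 1 (0.0503) or high-fat library 1 (0.0563), 3 (0.0624) or 4 (0.0637) and with no filter on low counts (0.0607). Cry2 (0.12 ± 0.09), Per1 (-0.33 ± 0.27), Per2 (0.47 ± 0.22) and Bmal1, listed as Arntl (-0.73 ± 0.38), did not pass, with adjusted p from 0.124 to 0.387, although Bmal1 passed (7.4e-05) with only the groups compared in the fit. Camera called 25 of 48 lists on this diet, 16 up and 9 down, among the latter bile acid (2 of 15 fell, camera adjusted p = 0.0398), periportal (5 of 14, 0.0419) and oxidative phosphorylation genes (1 of 21, 0.00564). With an estimated correlation these had adjusted p = 0.604 each, and over the list alone 2, 5 and 0 fell. Leaving out 1 library moved the fold by over 1.5 times for Cidea (7.94 without normal-diet library 4), Cyp2b9 (7.78) and Cyp2b10 (-5.45, both without normal-diet library 1) and Hsd3b5 (-9.89 without high-fat library 3). Median, mean and test differed in sign for 4 lists without a call: circadian clock, heat shock, vascular endothelial markers, and ubiquitin ligase components for E2F1 and Myc.

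Tumour pieces were compared with non-tumour pieces of high-fat-fed mice, separately in the non-exercised and the exercised arm. Oncofetal and tumour marker transcripts rose in tumours: Igdcc4, a cell surface protein of the immunoglobulin family, by 5.77 ± 0.67 in non-exercised and 6.44 ± 0.71 in exercised mice, the Golgi protein Golm1 by 3.74 ± 0.45 and 3.61 ± 0.45, and the progenitor marker Prom1 by 4.17 ± 0.55 and 4.01 ± 0.55. Sterol enzymes rose and mitochondrial enzymes fell, as for lanosterol synthase Lss (2.77 ± 0.31 and 2.73 ± 0.31) and the succinate dehydrogenase subunit Sdhb (-0.90 ± 0.11 and -0.71 ± 0.10). Without pairing the pieces of a mouse, 5164 genes passed in non-exercised mice, 2596 higher and 2568 lower, and in exercised mice 4986 passed, 2682 higher and 2304 lower. The arms shared 2024 higher calls (482.6 for independent lists) and 1797 lower calls (410.1), and no gene was called in opposite directions, where independent lists would share 414.6 and 477.4. Across genes, which are not independent replicates, the log2 fold changes of the arms had a Pearson r of 0.914.

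Proliferation genes were higher in tumours. Of 25 G2 and M phase genes 24 rose and 0 fell in each arm, also when adjusted over the list alone (medians 2.76 and 2.17). Camera gave adjusted p = 4.79e-23 in non-exercised and 5.06e-15 in exercised mice, and adjusted p = 0.503 and 0.586 with an estimated correlation. Ube2c rose by 3.12 ± 0.31 and 2.17 ± 0.31 and the centromere histone Cenpa by 1.94 ± 0.24 and 1.65 ± 0.24. Of 32 E2F targets 19 rose and 0 fell in non-exercised mice (camera p = 4.35e-06, estimated-correlation p = 0.585). In exercised mice 7 rose and 2 fell (camera p = 0.113, estimated-correlation p = 0.801), and counts in both arms were the same when adjusted over the list alone. E2f1 (0.15 ± 0.14 and -0.01 ± 0.14) and Myc (0.44 ± 0.46 and 0.18 ± 0.45) did not pass in either arm, with adjusted p of 0.442 and 0.965 and of 0.491 and 0.78. Of 26 Myc targets 4 rose and 1 fell in non-exercised mice, 2 and 0 when adjusted over the list alone (camera p = 0.187, estimated-correlation p = 0.773). In exercised mice 4 rose and 0 fell, 3 and 0 over the list alone (camera p = 0.3, estimated-correlation p = 0.835).

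Sterol synthesis genes rose, and genes of fat oxidation and respiration fell, in tumours of both arms. Of 23 cholesterol synthesis genes 22 rose and 0 fell in each arm, also over the list alone (medians 1.54 and 1.77). Camera gave 3.39e-14 and 1.05e-16 as adjusted p, and adjusted p = 0.585 and 0.586 with an estimated correlation. The demethylase Cyp51 rose by 2.36 ± 0.33 and 2.38 ± 0.33, and Dhcr7 by 2.40 ± 0.33 in exercised mice. Scd2, a fatty acid desaturase, rose by 4.91 ± 0.52 and 4.87 ± 0.52 and Pnpla3 by 2.88 ± 0.31 and 4.12 ± 0.35. Of 26 fatty acid oxidation genes 1 rose and 16 fell in non-exercised mice (2 and 19 adjusted over the list alone, camera p = 3.65e-05, estimated-correlation p = 0.585). In exercised mice 2 rose and 11 fell (2 and 16 over the list alone, camera p = 0.000108, estimated-correlation p = 0.679). Of 21 oxidative phosphorylation genes 21 fell in non-exercised and 18 in exercised mice, with none higher (21 and 19 adjusted over the list alone). Camera gave adjusted p = 1.06e-14 and 4.11e-10 for them, and adjusted p = 0.503 and 0.586 with an estimated correlation. The share of mitochondrially encoded counts was lower in the same libraries. Of 7 such genes 6 fell in non-exercised mice (camera p = 0.00193, estimated-correlation p = 0.585) and 4 in exercised mice (camera p = 0.0457, estimated-correlation p = 0.679), the same over the list alone. Of these mt-Cytb was at -0.90 ± 0.17 and -0.52 ± 0.17, with the call in exercised mice lost without exercised non-tumour library 1, 3 or 4 or exercised tumour library 1, 2 or 4 (adjusted p 0.0501 to 0.0878). With the mouse as a fixed block, the calls of mt-Cytb (-0.53, adjusted p = 0.108) and of the list (0.0936) were lost in exercised mice.

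Bile acid, pericentral and xenobiotic metabolism lists were lower in tumours. Of 15 bile acid genes 0 rose and 9 fell in non-exercised mice (1 and 12 adjusted over the list alone, camera p = 7.05e-05, estimated-correlation p = 0.585). In exercised mice 1 rose and 10 fell (1 and 11 over the list alone, camera p = 0.000418, estimated-correlation p = 0.679). The conjugating enzymes Slc27a5 (-1.03 ± 0.18 and -0.87 ± 0.18) and Baat (-1.22 ± 0.24 and -1.17 ± 0.24) were among them. Of 13 pericentral hepatocyte genes 8 fell in non-exercised mice (11 over the list alone, camera p = 0.00013, estimated-correlation p = 0.614). In exercised mice 9 fell (11 over the list alone, camera p = 7.31e-05, estimated-correlation p = 0.679), and none rose in either arm. Hepatocyte identity and periportal lists had no call. Of 18 hepatocyte identity genes 5 rose and 9 fell in non-exercised (6 and 9 over the list alone, camera p = 0.414, estimated-correlation p = 0.791) and 5 rose and 7 fell in exercised mice (5 and 8 over the list alone, camera p = 0.541, estimated-correlation p = 0.835). Of 14 periportal genes 3 rose and 8 fell in non-exercised (4 and 9 over the list alone, camera p = 0.0638, estimated-correlation p = 0.617) and 4 rose and 7 fell in exercised mice (4 and 8 over the list alone, camera p = 0.287, estimated-correlation p = 0.801). Alb (1.40 ± 0.23 and 1.25 ± 0.23) and the apolipoprotein Apoa1 (1.64 ± 0.23 and 1.62 ± 0.23) rose, and Hgd, an enzyme of tyrosine breakdown, fell in non-exercised mice (-1.43 ± 0.24). Of 17 xenobiotic metabolism genes 1 rose and 7 fell in non-exercised mice (1 and 9 over the list alone, camera p = 0.00627, estimated-correlation p = 0.585). In exercised mice 1 rose and 11 fell (1 and 13 over the list alone, camera p = 0.00287, estimated-correlation p = 0.586). Of 16 male-biased genes 6 fell in exercised mice (camera p = 0.00624, estimated-correlation p = 0.707) and 2 in non-exercised mice (camera p = 0.0129, estimated-correlation p = 0.722), as over the list alone. Hsd3b5, at -5.24 ± 1.55 in exercised mice, was at -0.38 (adjusted p = 0.826) without exercised non-tumour library 1, and at -2.47 (adjusted p = 0.357) in limma-voom with the mouse as a block.

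Tumour, stress and stromal markers also differed. Of 29 measured liver tumour markers 20 rose and 1 fell in non-exercised mice (21 and 1 over the list alone, camera p = 5.72e-07, estimated-correlation p = 0.585). The exercised arm had 22 higher and 1 lower (24 and 1 over the list alone, camera p = 2.12e-08, estimated-correlation p = 0.586). Bex1 rose by 6.37 ± 0.88 in exercised mice and the trypsin inhibitor Spink1 by 7.54 ± 1.21 in non-exercised mice. The kinase inhibitor Cdkn2b rose by 5.93 ± 0.67 and 5.85 ± 0.71. Within its p53 and senescence list 6 of 18 genes rose and 1 fell in non-exercised mice (camera p = 0.0225, estimated-correlation p = 0.722). In exercised mice 7 rose and 1 fell (camera p = 0.00504, estimated-correlation p = 0.679), and both arms had the same counts over the list alone. Asparagine synthetase Asns rose by 4.70 ± 0.89 and 4.43 ± 0.92, a call lost in exercised mice in limma-voom with the mouse as a block (3.84, adjusted p = 0.0558). Its unfolded protein response list had 5 higher and 0 lower of 17 in non-exercised mice (4 and 0 over the list alone, camera p = 0.0281, estimated-correlation p = 0.722). In the exercised arm 6 were higher and 1 lower (camera p = 0.0117, estimated-correlation p = 0.679). Among macrophage markers, Folr2 of resident cells fell (-1.57 ± 0.45 and -1.53 ± 0.45) while Fabp5 (3.94 ± 0.58 and 4.50 ± 0.60) and the lipase Lpl (1.76 ± 0.28 and 2.33 ± 0.28) rose. Resident markers had 0 higher and 5 lower of 13 in each arm, as over the list alone (camera p = 0.00743, estimated-correlation p = 0.722 in non-exercised mice, camera p = 0.00347, estimated-correlation p = 0.679 in exercised mice). Of 14 markers of lipid-associated macrophages 4 rose in non-exercised mice (camera p = 0.0843, estimated-correlation p = 0.745, and camera adjusted p = 0.031 with the mouse as a fixed block) and 5 in exercised mice (camera p = 0.00287, estimated-correlation p = 0.679), with none lower, as over the list alone. Fatty acid synthesis genes had 7 higher and 2 lower of 20 in non-exercised (7 and 2 over the list alone, camera p = 0.14, estimated-correlation p = 0.773) and 8 and 1 in exercised mice (10 and 1 over the list alone, camera p = 0.00484, estimated-correlation p = 0.679). Of 6 adipocyte markers 0 rose and 4 fell in non-exercised (0 and 5 over the list alone, camera p = 0.0256, estimated-correlation p = 0.585) and 1 rose and 1 fell in exercised mice (1 and 2 over the list alone, camera p = 0.398, estimated-correlation p = 0.801). Of 22 stellate cell and fibrosis genes 6 rose and 0 fell in each arm (3 and 0 over the list alone, camera p = 0.357, estimated-correlation p = 0.853 in non-exercised mice, and 6 and 0, camera p = 0.0222, estimated-correlation p = 0.801 in exercised mice). Leaving out 1 library moved the fold by over 1.5 times in non-exercised mice for Igdcc4 (6.37 without non-tumour library 2), Cdkn2b (5.18 without tumour library 1) and Folr2 (-2.16 without tumour library 3). In exercised mice this held without non-tumour library 2 for Igdcc4 (7.81), Bex1 (9.06) and Scd2 (5.66), and without tumour library 1 for Bex1 (5.43), Fabp5 (3.62) and Asns (3.14).

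Clock genes changed in both directions in tumours. Of 19 members 2 rose and 5 fell in non-exercised mice (camera p = 0.11, estimated-correlation p = 0.585) and 2 rose and 3 fell in exercised mice (camera p = 0.222, estimated-correlation p = 0.679), as over the list alone. Hlf (-0.89 ± 0.14 and -0.81 ± 0.14) and Tef (-1.12 ± 0.24 and -0.88 ± 0.23), both output regulators related to Dbp, fell, and Rora rose in exercised mice (0.50 ± 0.12). The Tef call in exercised mice was lost when exercised non-tumour libraries 1 and 2 were left out together (0.0791). Cry2 fell in non-exercised mice (-0.47 ± 0.09, adjusted p = 0.000732) and was at -0.15 ± 0.09 in exercised mice (adjusted p = 0.184). Cry1, Per1, Per2, Per3, Nr1d1, Dbp and Bmal1 did not pass in either arm, with values from -0.70 (Dbp, SE 0.51) to 0.47 (Bmal1, SE 0.37) in non-exercised mice and from -0.20 (Dbp, SE 0.47) to 0.55 (Bmal1, SE 0.39) in exercised mice. With only the groups compared in the fit, Nr1d1 (0.028) and Bmal1 (0.0279) passed in non-exercised mice. With the mouse as a fixed block, Nr1d1 (-0.54, adjusted p = 0.0248), Bmal1 (0.45, 0.04) and Per2 (0.33, 0.0227) passed in non-exercised mice, and Bmal1 (0.58, 0.0227) and Per2 (0.28, 0.0413) in exercised mice; Nr1d1 also passed in non-exercised mice in limma-voom with this block (0.0497). Camera called 17 of 48 lists in non-exercised mice, 6 up and 11 down, and 19 in exercised mice, 10 up and 9 down. Median, mean and test differed in sign for 3 lists without a call in the former (glucocorticoid response, heat shock, NRF2 targets). In the latter this held for 4: neutrophil and mesothelial markers, glycolysis and hypoxia, and nuclear-retained RNAs.

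**Figure D2:**
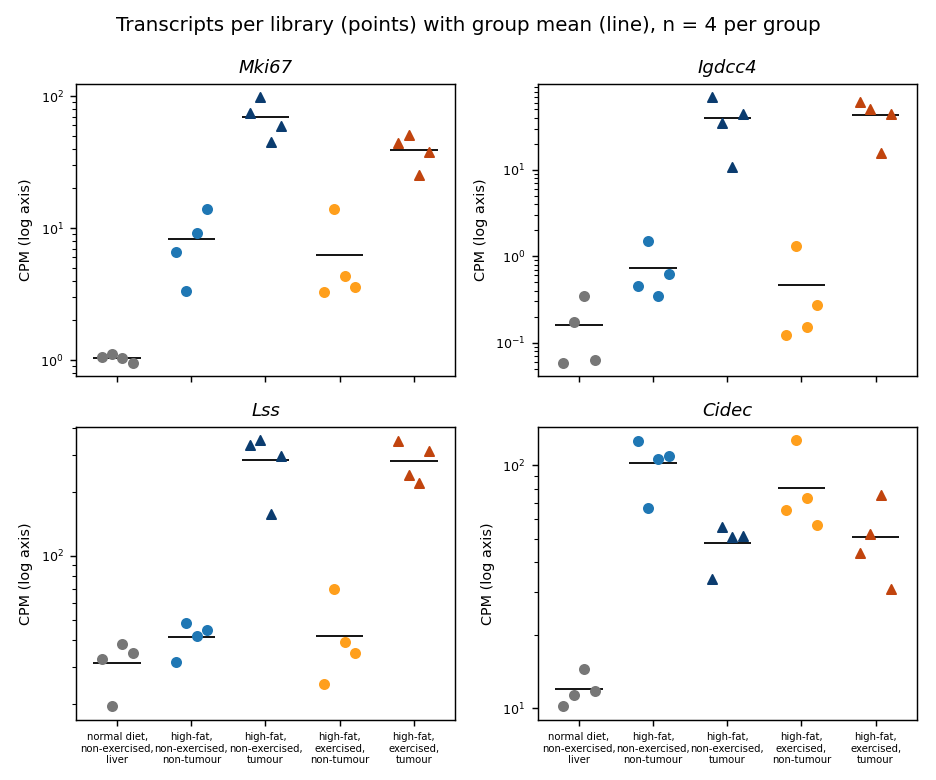
CPM (log axis) of Mki67, Igdcc4, Lss and Cidec in each library (points) with the group mean (line), 4 libraries per group. Mki67 lies at 25.3 to 98.5 CPM in the 8 tumour pieces and at 3.28 to 13.9 CPM in the 8 non-tumour pieces on the high-fat diet, and Lss at 158 to 350 CPM in the tumour pieces and at 19.5 to 69.4 CPM in the other libraries.

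Exercised and non-exercised mice on the high-fat diet were compared in non-tumour liver. Training cannot be told apart here from the last run. Usp2, a deubiquitinating enzyme whose expression is rhythmic, rose from 2.38 ± 0.537 to 18.6 ± 14.7 CPM (mean ± SD, n = 4; 2.96 ± 0.39, adjusted p = 0.00654). Exercised library 1 held 40.3 CPM of Usp2 and the others 7.61 to 14.4, and without it the log2 fold change was 2.27 (adjusted p = 0.000562). Mbd1, which binds methylated DNA, rose from 48 ± 6.66 to 116 ± 30.9 CPM (1.27 ± 0.20, adjusted p = 0.0396). These were the only 2 genes edgeR called, with 1203 at an unadjusted p under 0.05 (721 by chance), and DESeq2 called 107, 91 higher and 16 lower. All 4 exercised libraries lay above all 4 others for both genes. On GRCm39, Usp2 is ENSMUSG00000032010.16, chromosome 9, start 43978318, end 44006924 and Mbd1 is ENSMUSG00000024561.12, chromosome 18, start 74400676, end 74415803.

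The circadian clock list moved in non-tumour liver of exercised mice. None of its 19 members passed over all genes tested in edgeR, and 10 rose and 2 fell when adjusted over the list alone (median 0.42, camera p = 3.93e-07, and p = 0.043 with an estimated correlation). Dbp was at 2.38 ± 0.50 (adjusted p = 0.141 over all genes, 0.000822 over the list alone), Per3 at 1.48 ± 0.31, Per1 at 1.07 ± 0.27, Per2 at 0.82 ± 0.22 and Cry2 at 0.30 ± 0.09, all passing over the list alone. Nr1d1 (0.56 ± 0.25) and Cry1 (-0.51 ± 0.35) did not pass in either way, and Bmal1 was lower over the list alone (-1.04 ± 0.39, 0.0261). Ciart (3.96 ± 0.75), a repressor of the clock, Tef (1.21 ± 0.23) and Npas2, a partner of Bmal1 (-1.86 ± 0.44), were chosen after their values were seen and also passed over the list alone. DESeq2 called Per1, Per2, Per3, Dbp, Tef, Ciart and Npas2. All 4 exercised libraries lay beyond all 4 others for Dbp, Per1, Per2, Per3, Cry2, Nr1d1 and Bmal1. With each library left out in turn, the adjusted p of the list lay between 9.07e-08 and 1.99e-05 at the preset correlation and between 0.0269 and 0.193 with an estimated correlation. The latter was over 0.05 without non-exercised library 1 (0.114), 2 (0.0526) or 3 (0.0923) or exercised library 2 (0.193) or 4 (0.0885).

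Glucocorticoid response, glucose metabolism and hepatocyte lists were higher in the same libraries by camera. Of 14 glucocorticoid response genes 8 rose and 0 fell when adjusted over the list alone and none over all genes tested in edgeR, while DESeq2 called Fkbp5, Zbtb16 and Per1 (median 0.66, camera p = 1.97e-07, estimated-correlation p = 0.106). The enzyme Tat was at 0.90 ± 0.33 and Errfi1, a feedback inhibitor of growth factor signalling, at 0.41 ± 0.14. Chosen after their values were seen, Fkbp5 (1.86 ± 0.53, 0.0115 over the list alone), a chaperone of the glucocorticoid receptor, the metallothionein Mt2 (2.90 ± 0.94, 0.0173), Zbtb16 (3.12 ± 0.86, 0.0115, and 2.39 without exercised library 2) and Klf9 (0.60 ± 0.19, 0.0171) also passed over the list alone. Of 16 glucose metabolism genes 3 rose when adjusted over the list alone (camera p = 0.00732, estimated-correlation p = 0.513), among them Lpin1 (2.40 ± 0.53) and the transcription factor Foxo1 (0.91 ± 0.21), chosen after their values were seen. Hepatocyte identity genes were higher by camera (1 of 18 passed over the list alone, camera p = 4.11e-06, estimated-correlation p = 0.106), with Alb at 0.31 ± 0.22. The member that passed was the tryptophan dioxygenase Tdo2 (0.51 ± 0.14, 0.0365, also called by DESeq2), chosen after its values were seen. Also higher were xenobiotic metabolism genes (3 of 17, camera p = 0.000656, estimated-correlation p = 0.376) and male-biased genes (1 of 16, camera p = 0.00567, estimated-correlation p = 0.687).

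Several immune and matrix lists were lower in non-tumour liver of exercised mice by camera, with no member passing over all genes tested in edgeR. DESeq2 called 4 MHC class II genes (Cd74, Ciita, H2-Ab1 and H2-Eb1) and no member of the other lists here. Of 9 MHC class II genes, which present antigen, 7 fell when adjusted over the list alone (median -1.40, camera p = 1.5e-10, estimated-correlation p = 0.183). They included Cd74 (-1.40 ± 0.41, 0.00636 over the list alone) and H2-Aa (-1.49 ± 0.44), as well as Ciita (-1.59 ± 0.39, 0.00584), which was chosen after its values were seen. Of 22 stellate cell and fibrosis genes all had lower values and 0 passed over the list alone (median -0.60, camera p = 5.37e-09, estimated-correlation p = 0.413). The 14 markers of lipid-associated macrophages were lower (2 passing over the list alone, median -0.81, camera p = 1.97e-07, estimated-correlation p = 0.356). So were 15 T and NK cell markers (0 passing, median -1.11, Ccl5 -1.80 ± 0.58, camera p = 7.96e-06, estimated-correlation p = 0.513) and 20 interferon response genes (0 passing, median -0.36, camera p = 1.84e-05, estimated-correlation p = 0.376). Mesothelial markers had 5 of 5 members lower (median -1.35, camera p = 0.0127, estimated-correlation p = 0.376), and cholangiocyte and progenitor markers 12 of 12 (median -0.31, camera p = 0.0287, estimated-correlation p = 0.672), with none passing. Other immune lists had no call: resident macrophage markers (median -0.08, camera p = 0.485, estimated-correlation p = 0.902), neutrophil markers (-0.12, camera p = 0.485, estimated-correlation p = 0.887) and B and plasma cell markers (-0.18, camera p = 0.892, estimated-correlation p = 0.988). Sinusoidal endothelial markers had a median of 0.10 (camera p = 0.427, estimated-correlation p = 0.863) and mitochondrially encoded genes one of 0.12 (camera p = 0.092, estimated-correlation p = 0.698).

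E2f1 (0.19 ± 0.14, adjusted p = 0.786) and Myc (0.86 ± 0.46, adjusted p = 0.653) did not pass in non-tumour liver. Of 32 E2F targets none passed in either way, with a median of 0.13 (camera p = 0.0287, estimated-correlation p = 0.726), a camera call lost without non-exercised library 1 (0.0716) or 2 (0.396) or exercised library 1 (0.0912) or 2 (0.654). G2 and M phase genes had a median of -0.19 (Mki67 -0.39 ± 0.44, camera p = 0.0631, estimated-correlation p = 0.795). Camera called the list without non-exercised library 1 (0.0159) or 2 (0.000202) or exercised library 2 (4.17e-08), and the direction turned without non-exercised library 4 (0.746). Myc targets had a median of -0.01 (camera p = 0.471, estimated-correlation p = 0.869). Camera also called unfolded protein response (0.0103), acute phase (0.0037), pericentral (0.0484) and periportal genes (0.0203) as higher and fatty acid synthesis (0.00815), senescence-associated secretion (0.0133), NRF2 target (0.0107) and liver tumour marker genes (0.0475) as lower. These had adjusted p from 0.546 to 0.742 with an estimated correlation, and over the list alone 1 unfolded protein response gene rose and 1 fatty acid synthesis gene fell. In all, camera called 22 of 48 lists, 11 up and 11 down, and 9 calls held with each library left out in turn. Median, mean and test differed in sign for 3 lists without a call: Myc targets, resident macrophage markers and neutrophil markers. Usp2 lost its call without non-exercised library 1 (0.0685) or 3 (0.0712) and with only the groups compared (0.244), and the number of genes called was 0 in these cases. Mbd1 lost its call without any of non-exercised libraries 1 to 4 (0.363, 0.093, 0.207 and 0.305) or exercised library 1 (0.264) or 4 (0.132), leaving 1 gene without exercised library 1 or 4 or non-exercised library 2 or 4, whereas 72 genes passed without exercised library 3.

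Exercised and non-exercised mice were compared again in tumour pieces. Cry2, a repressor of the clock, rose from 17.4 ± 1.88 to 26.6 ± 2.89 CPM (mean ± SD, n = 4; 0.62 ± 0.09, adjusted p = 0.0232), and Tef from 22.7 ± 9.14 to 62.4 ± 8.98 CPM (1.46 ± 0.24, adjusted p = 0.0423). Cd300lg, a receptor of endothelial cells, rose from 11.4 ± 2.26 to 19.9 ± 1.68 CPM (0.81 ± 0.13, adjusted p = 0.0423). These were the 3 genes edgeR called, with 1252 at an unadjusted p under 0.05 (721 by chance), and DESeq2 called 79, 61 higher and 18 lower. All 4 exercised tumours lay above all 4 others for each. On GRCm39, Cry2 is ENSMUSG00000068742.12, chromosome 2, start 92233991, end 92264388, Tef is ENSMUSG00000022389.16, chromosome 15, start 81686622, end 81711064 and Cd300lg is ENSMUSG00000017309.12, chromosome 11, start 101932335, end 101946446.

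The clock list also moved in tumours of exercised mice. Over all genes tested 2 of its 19 members rose, and 11 rose and 4 fell when adjusted over the list alone (median 0.62, camera p = 1.72e-09, and p = 0.00554 with an estimated correlation). Dbp was at 2.88 ± 0.52 (adjusted p = 0.0634 over all genes, 0.0002 over the list alone) and at 2.05 (adjusted p = 0.108) without exercised tumour library 1, Nr1d1 was at 1.24 ± 0.25 (0.000451 over the list alone), Per1 at 1.20 ± 0.27, Per2 at 0.77 ± 0.21 and Per3 at 1.45 ± 0.31. Bmal1 (-0.96 ± 0.38) and Cry1 (-0.95 ± 0.35) were lower over the list alone (0.0288 and 0.0226), as was Npas2 (-1.60 ± 0.41), while Ciart (3.97 ± 0.86) was higher; both were chosen after their values were seen. Dbp, Nr1d1, Nr1d2, Per1, Per3, Cry2, Tef, Ciart and Npas2 were called by DESeq2. With each library left out in turn, the adjusted p of the clock list with an estimated correlation stayed between 0.00278 and 0.0331.

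**Figure D3:**
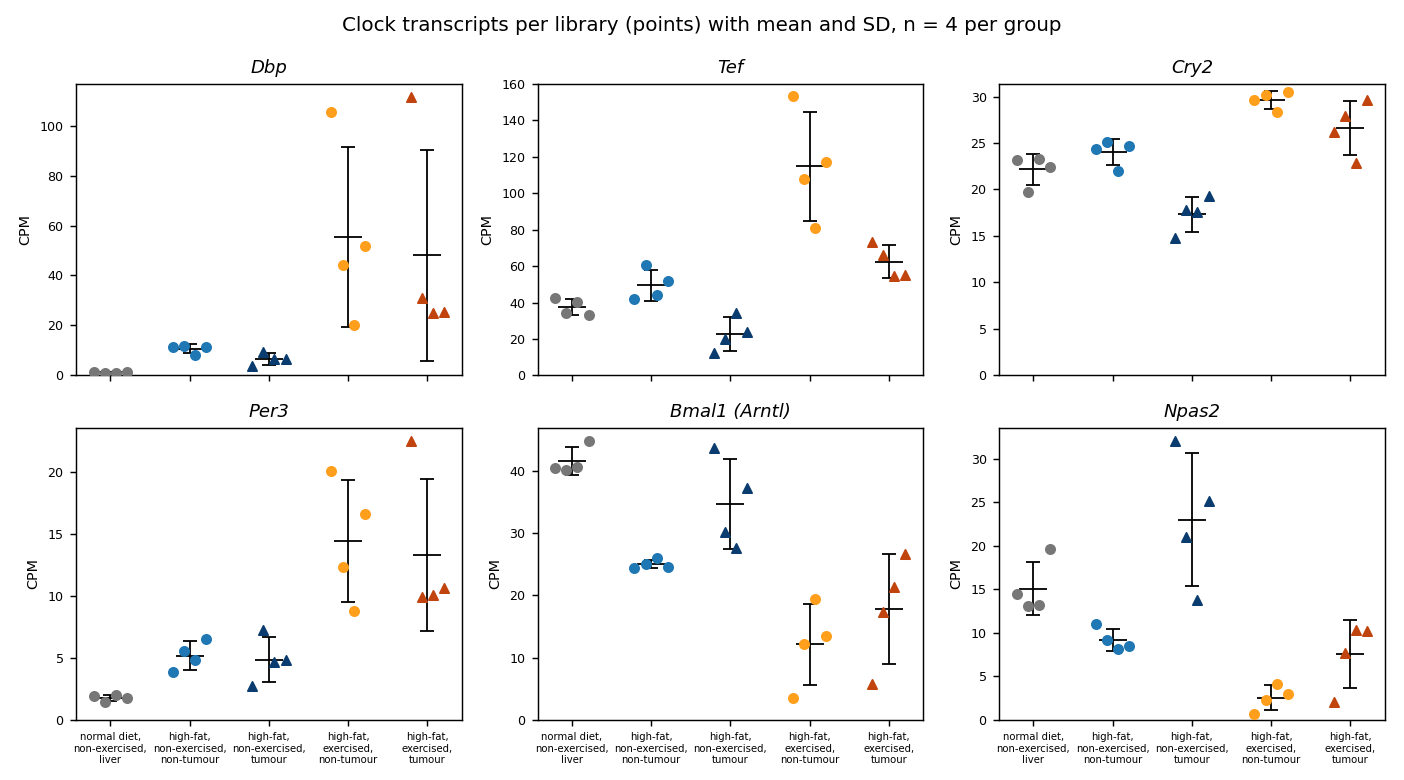
CPM of Dbp, Tef, Cry2, Per3, Bmal1 (Arntl) and Npas2 in each library (points), with mean and SD of the 4 libraries of each group. Dbp is at 6.51 ± 2.36 CPM in non-exercised and 48.1 ± 42.2 CPM in exercised tumours, and exercised tumour library 1 stands at 111 CPM.

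Glucocorticoid response, glucose metabolism and hepatocyte lists were higher by camera in exercised tumours too. Of 14 glucocorticoid response genes 7 rose and 0 fell when adjusted over the list alone and none over all genes tested in edgeR, while DESeq2 called Sgk1, Klf9 and Per1 (median 0.95, camera p = 3.55e-10, estimated-correlation p = 0.052), with Errfi1 at 0.27 ± 0.14 and Lcn2 at 0.18 ± 0.63. Fkbp5 (1.38 ± 0.52), Mt2 (3.11 ± 0.93), the kinase Sgk1 (0.97 ± 0.22) and Klf9 (0.81 ± 0.19) passed over the list alone (0.0317, 0.0127, 0.00192 and 0.00192) and were chosen after their values were seen. Of 16 glucose metabolism genes 6 rose when adjusted over the list alone (camera p = 2.26e-06, estimated-correlation p = 0.137), including Pck1 (1.46 ± 0.38, 0.00978 over the list alone, and 2.08 without non-exercised tumour library 3, where it passed over all genes with 0.0129), the entry enzyme of gluconeogenesis. Gys2 (0.96 ± 0.23), the glycogen synthase of liver, and Lpin1 (1.76 ± 0.52) were among them and were chosen after their values were seen. Of 14 periportal hepatocyte genes 5 rose over the list alone (camera p = 5.53e-06, estimated-correlation p = 0.137), with arginase Arg1 at 0.61 ± 0.15. Sds, a serine dehydratase chosen after its values were seen, was at 2.12 ± 0.36 (adjusted p = 0.0508 over all genes, 0.000197 over the list alone). Hepatocyte identity genes were also higher by camera (3 of 18 passing over the list alone, median 0.27, camera p = 4.05e-07, estimated-correlation p = 0.058), with Alb at 0.16 ± 0.22. RNA quality lists moved beside them. Of the mitochondrially encoded genes 6 of 7 rose over the list alone (mt-Co1 0.36 ± 0.16, mt-Cytb 0.46 ± 0.17, camera p = 4.02e-06, estimated-correlation p = 0.183). Nuclear-retained RNAs were lower (Malat1 -0.25 ± 0.13, camera p = 0.0273, estimated-correlation p = 0.183).

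Cell cycle lists were lower by camera in exercised tumours, with no member called over all genes tested in edgeR. All 25 G2 and M phase genes had lower values and 1 fell when adjusted over the list alone (median -0.90, camera p = 2.93e-16, estimated-correlation p = 0.183), with Mki67 at -0.82 ± 0.40 and Top2a at -0.89 ± 0.34. The gene that passed over the list alone was Kif11 (-1.02 ± 0.26, 0.0239), a spindle motor, named after its values were seen and the 1 member of the 2 lists that DESeq2 called over all genes (0.0193). Of 32 E2F targets 3 had higher and 29 lower values and none passed in either way (median -0.26, camera p = 5.53e-06, estimated-correlation p = 0.412), with Pcna at -0.06 ± 0.10. E2f1 was at 0.03 ± 0.14 (adjusted p = 0.972, and a fold change of 0 with upper-quartile factors) and Myc at 0.60 ± 0.45 (adjusted p = 0.74). Myc targets had a median of -0.01 (camera p = 0.995, estimated-correlation p = 0.998).

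Immune lists were lower by camera in exercised tumours too. Interferon response genes had a median of -0.46 (2 of 20 passing over the list alone, camera p = 5.07e-08, estimated-correlation p = 0.166). MHC class II genes had one of -0.81 (1 of 9 passing, Cd74 -0.81 ± 0.40, H2-Aa -0.81 ± 0.43, camera p = 3.94e-05, estimated-correlation p = 0.369). T and NK cell markers had a median of -0.75 (0 of 15 passing, camera p = 0.00143, estimated-correlation p = 0.646). The MHC class II call was lost without non-exercised tumour library 3 (0.0614), as was that of T and NK cells (0.718). Camera also called oxidative phosphorylation (0.000517), xenobiotic (0.00137), unfolded protein response (0.00144), male-biased (0.00968), lipid droplet, fatty acid oxidation and bile acid genes (0.0273 each) and adipocyte markers (0.00137) as higher. Stellate cell and fibrosis genes (0.00865) and markers of lipid-associated macrophages (0.0273) were lower. These had adjusted p from 0.183 to 0.792 with an estimated correlation, and 2 genes each rose over the list alone for the xenobiotic, unfolded protein and adipocyte lists and none for the others. In all, camera called 22 of 48 lists, 14 up and 8 down, and 11 calls held with each library left out in turn, among them those of the clock, E2F, G2 and M, glucocorticoid and glucose lists. Median, mean and test differed in sign for 5 lists without a call: Myc targets, liver tumour markers, and markers of resident macrophages, B and plasma cells and mesothelium. The call of Cry2 was lost without non-exercised tumour library 1 (0.149) or 2 (0.142) or exercised tumour library 1 (0.0835), 2 (0.122) or 4 (0.076). Tef and Cd300lg lost theirs without the same libraries and without non-exercised tumour library 4, with RLE factors (0.0557), with upper-quartile factors (0.0654) and with a filter of 1 CPM in 4 libraries (0.0508), and Tef also with no filter on low counts (0.112). With only the groups compared all 3 lost theirs (0.593 each). Without these libraries, adjusted p was 0.076 to 0.205 for Tef and 0.108 to 0.264 for Cd300lg. The number of genes called was 0 without non-exercised tumour library 1 or 2 or exercised tumour library 1 or 2, 1 without exercised tumour library 4, 31 without non-exercised tumour library 3 and 41 without exercised tumour library 3.

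**Figure D4:**
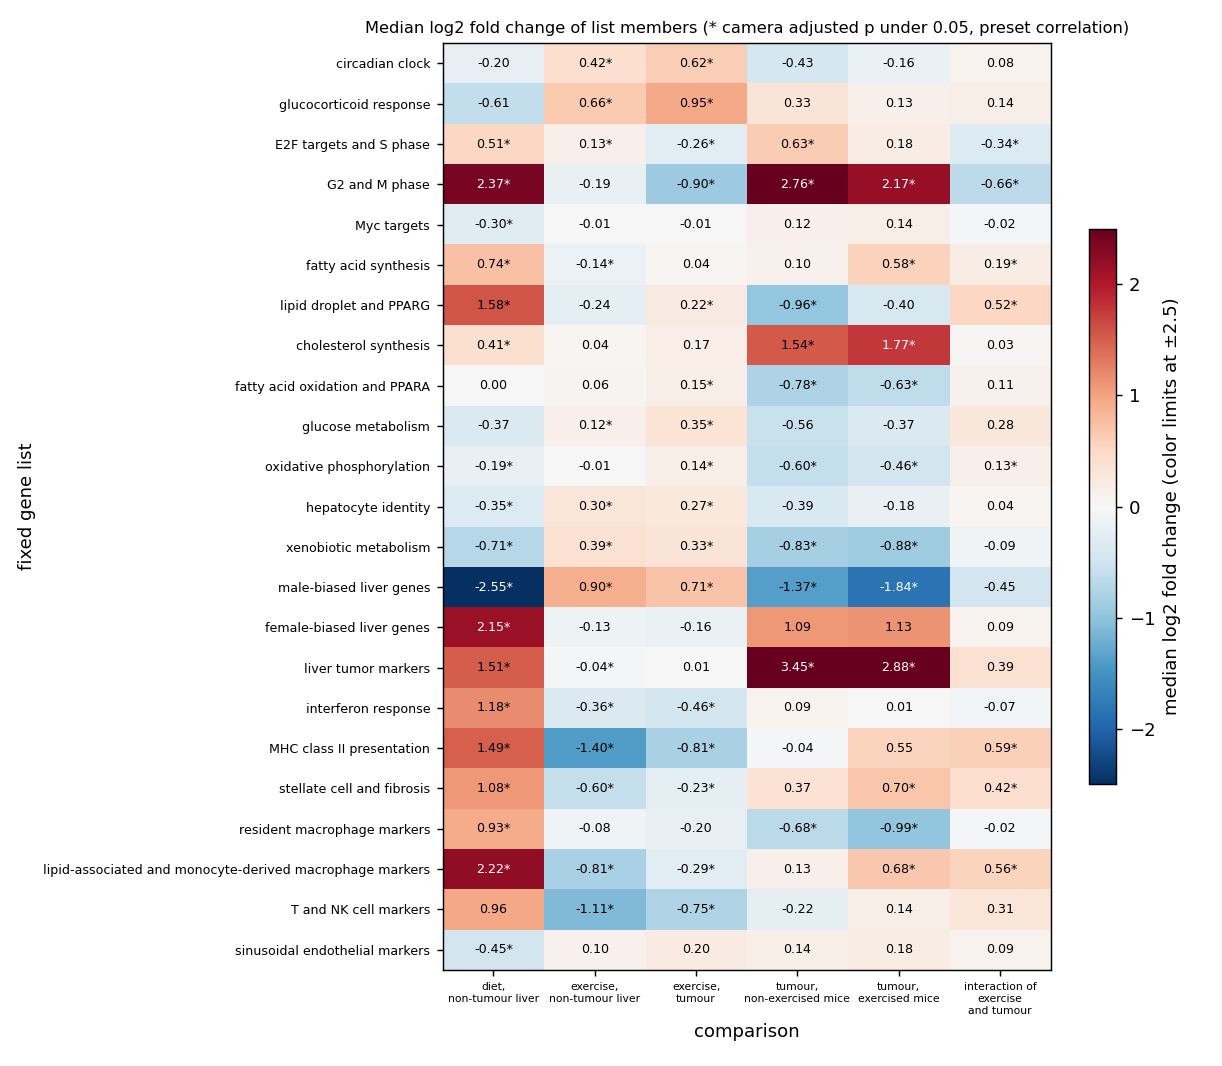
Median log2 fold change of the members of 23 of the 48 gene lists (vertical) in the 6 comparisons (horizontal), with color limits at 2.5 in either direction and an asterisk where the camera adjusted p at the preset correlation was under 0.05. The clock list has medians of 0.42 and 0.62 in the exercise comparisons and the G2 and M phase list 2.37 with the high-fat diet, 2.76 and 2.17 in tumours and -0.90 with exercise in tumours.

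The difference of the exercise effect between tumour and non-tumour pieces was tested as an interaction. Proliferation lists had more negative exercise values in tumours, with a median difference of -0.66 for G2 and M phase genes (Mki67 -0.43 ± 0.60, Top2a -0.38 ± 0.51, camera p = 2.47e-08, estimated-correlation p = 0.722). For E2F targets it was -0.34 (Pcna -0.10 ± 0.14, camera p = 1.29e-11, estimated-correlation p = 0.362). The lipid droplet list had a positive difference (0.52, camera p = 0.000267, estimated-correlation p = 0.362), as had adipocyte markers (0.50, camera p = 0.00106, estimated-correlation p = 0.362). The clock list (0.08, camera p = 0.417, estimated-correlation p = 0.898) and Myc targets (-0.02, camera p = 0.504, estimated-correlation p = 0.975) had no call. E2f1 (-0.16 ± 0.20), Myc (-0.25 ± 0.64) and the clock genes, from -0.44 (Cry1, SE 0.49) to 0.68 (Nr1d1, SE 0.35), did not pass, with adjusted p = 1 for Dbp (0.50 ± 0.69). No gene passed in edgeR, DESeq2 or limma-voom, with 293 genes at an unadjusted p under 0.05 in edgeR, fewer than the 721 of chance. The smallest unadjusted p were those of St8sia3 (2.55 ± 0.66), Pdgfd (1.32 ± 0.35), Shoc2 (-0.42 ± 0.11), Gm15564 (-1.48 ± 0.40) and Cd300lg (0.68 ± 0.19). Camera called 15 of 48 lists, 11 up and 4 down, and 3 calls held with each library left out in turn: E2F targets, adipocyte markers and lipid droplet genes. The other 12 were lost without 1 or more of the 16 libraries, that of G2 and M without exercised non-tumour library 2 (0.181). Median, mean and test differed in sign for 6 lists without a call: bile acid genes, immediate early genes, p53 targets, B and plasma cell markers, female-biased genes and ubiquitin ligase components.

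Across genes, which are not independent replicates, the exercise effects in tumour and non-tumour pieces, which come from the same mice, had a Pearson r of 0.489. The diet and exercise effects in non-tumour liver had an r of -0.56, but both use the non-exercised non-tumour libraries. Unchanged groups simulated against those libraries gave a mean r of -0.492, and the covariance was -0.193 against -0.0435 simulated, a difference of -0.149. Dividing the shared libraries between the comparisons gave a mean r of -0.341 over 6 splits (-0.42 to -0.207). Diet and exercise in tumours, which share no library but the non-exercised mice, had an r of -0.312.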

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

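The tests of list differences between tissues were planned and the test of the tumour cell share was set before its result was seen; the tests of clock phase, of the pieces numbered 1, of spread between tumour pieces, of immune and other cell type scores and of other splits of the libraries were chosen after the result was seen.

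Single libraries stood far from the others of their group in 6 of 100 groups of values, where chance gives about 1 in 20. Dbp was at 111 CPM in exercised tumour library 1 and at 24.9 to 30.8 in the others, and Per3 at 22.6 CPM there and 9.94 to 10.6 in the others. Exercised non-tumour library 2 held Mki67 at 13.9 CPM (others 3.28 to 4.34), the tumour marker Igdcc4 at 1.33 CPM (others 0.121 to 0.271) and a G2 and M score of 0.341 (others -1.23 to -1.04). Bmal1 (Arntl) was at 45 CPM in normal-diet library 4, against 40.2 to 40.8.

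Exercise effects differed between tumour and non-tumour pieces for 15 of 48 lists by camera at the preset correlation. The effect was lower in tumours for E2F targets (adjusted p = 1.29e-11), G2 and M phase (2.47e-08), nuclear-retained RNAs (0.0479) and erythroid markers (0.0479). It was higher in tumours for lipid droplet (0.000267) and fatty acid synthesis genes (0.00844), adipocyte markers (0.00106), oxidative phosphorylation (0.00106), mitochondrially encoded genes (0.0123), NRF2 targets (0.00987), stellate cell and fibrosis genes (0.00645), and markers of lipid-associated macrophages (0.00987), vascular endothelium (0.0112) and mesothelium (0.0421), and for MHC class II genes (0.0409). With an estimated correlation none of the 15 calls held, with adjusted p from 0.362 to 0.818 among them. Leaving out 1 of the 16 libraries at a time ended 12 of the calls: nuclear-retained RNAs in 10 cases, MHC class II in 9, mitochondrially encoded genes in 8, erythroid in 7 and mesothelial markers in 6, stellate cell genes and lipid-associated macrophages in 5 each, NRF2 targets in 4, fatty acid synthesis and oxidative phosphorylation in 3 each, and vascular endothelium (0.0875 without exercised tumour library 1) and G2 and M (0.181 without exercised non-tumour library 2) in 1 each. With the mouse as a fixed block the call of mitochondrially encoded genes was lost (0.0697).

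Clock transcripts moved by the time at which they peak. In exercised mice the 5 that peak opposite to Dbp (Bmal1, Clock, Npas2, Nfil3, Cry1) had a median log2 fold change of -0.95 in tumours (SD over the 5: 0.50) and of -0.51 (SD 0.70) in non-tumour liver, with 5 of 5 lower in each tissue and a lower joint score (-0.98 and -0.89, exact permutation p = 0.0286 in each), which argues against a joint rise; in non-tumour liver the median alone, within its SD, left this open, and the score was added after that was seen. The score of evening minus morning transcripts was higher in exercised mice by 2.47 in tumours and 2.2 in non-tumour liver (exact permutation p = 0.0286 in each, the smallest that 70 assignments allow), and 6 of 6 exercised pieces not numbered 1 lay above the highest non-exercised piece of their tissue, which argues against pieces numbered 1 carrying the difference. It was also higher by 1.78 with the high-fat than with the normal diet (exact permutation p = 0.0286), with group means of -2.03 ± 0.1 (SD, n = 4) on the normal diet, -0.25 ± 0.29 and 1.95 ± 1.05 in non-exercised and exercised non-tumour liver, and -1.06 ± 0.6 and 1.4 ± 1.19 in the tumours of these arms. A different hour of sampling, the last run and training cannot be told apart. The labels place the high-fat mice on 1 day within 2 h of that run without a clock time. A shift of the clock by exercise is a hypothesis.

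The G2 and M genes of exercised tumours had a median of -0.90 (SD over 25 genes: 0.22). A smaller tumour cell share would lower other tumour genes alike. The 123 genes higher in both tumour comparisons by a like amount had a median of -0.28 (SD 0.49), above the bound of -0.67. They had to be high in exercised tumours, where some tumour-low lists rose by camera, so a smaller share stays open. So does spread between single tumour pieces. G2 and M and E2F scores differed by -0.82 and -0.27 in exercised tumours (exact permutation p = 0.0571 and 0.143). Same-numbered tumours of the arms are different mice and were not paired. Slower division with exercise is a hypothesis and may be only share or spread.

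A joint score over 60 genes of 4 lists chosen because they were lower (MHC class II, stellate cell, lipid-associated macrophage, T and NK cell) differed by -0.85 in exercised non-tumour liver (exact permutation p = 0.0571). Resident macrophage, neutrophil and B cell scores differed by 0.39, 0.21 and -0.04 (exact permutation p = 0.0571, 0.857 and 0.914). A lower share of all non-hepatocyte cells would lower sinusoidal endothelial markers too; their score minus the score of the 4 lists was higher by 0.92 in exercised mice (exact permutation p = 0.0857), and cholangiocyte, mesothelial and vascular endothelial scores differed by -0.37, -0.97 and -0.19 (exact permutation p = 0.314, 0.143 and 0.0857), so this cannot be told apart with 4 libraries in each arm. High values in the non-exercised non-tumour libraries alone cannot be told apart either, since the score differed by -0.42 in tumours of the same mice with an exact permutation p of 0.314. Fewer immune and matrix cells with exercise is a hypothesis.

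Other splits of the 8 libraries into groups of 4 showed whether chance can be excluded as the origin of a count of calls. It can for the diet, where 1 of 35 splits, the real one, gave as many as 3740 genes and the highest other 0. For tumours of non-exercised and exercised mice they cannot decide (real 5164 and 4986, highest other 1505 and 2215), as pieces were paired by mouse. Of the 8 splits that part each mouse's pieces, too few for a share under 0.05, only the real one gave any genes. Chance cannot be excluded for exercise in non-tumour liver, where 3 of 35 splits gave at least the real 2 genes. The highest other, 286, set exercised libraries 1, 3 and 4 with non-exercised library 2 against the rest. Nor can it for exercise in tumours, where 8 of 35 gave at least the real 3 and the highest other, 889, set libraries 1 and 2 of both arms against 3 and 4. These large counts point to a structure of the samples other than the arms, for which the labels give no batch. For the interaction this says nothing: with a real count of 0, all 100 regroupings give at least as many by construction (highest other 31).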

How the results depend on the processing

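Leaving out both tumour pieces numbered 3 or exercised non-tumour pieces numbered 1 and 2, leaving out libraries in list tests, and the block with an estimated correlation were chosen after seeing the data; the other alternatives were planned. Counts of changed genes stayed within 1.5 times of the value given for the diet (3740, settings 2823 to 4483, each library left out 2713 to 3616), for tumours of non-exercised mice (5164, 4272 to 6048, 3753 to 5938) and of exercised mice (4986, 3432 to 5751, 3731 to 5536), and the interaction had 0 under all. The counts for exercise depended on most settings. In non-tumour liver (2 genes) DESeq2 gave 107, no filter 1, only the groups compared 0, and leaving out exercised non-tumour pieces 1 and 2 gave 1, with 0 to 72 when each library was left out. In tumours (3 genes) RLE and upper-quartile factors and a filter of 1 CPM in 4 libraries gave 1 each, only the groups compared 0, DESeq2 79 and leaving out both tumour pieces 3 gave 52, with 0 to 41 when each library was left out. DESeq2 kept the 2 and the 3 genes. The fit of only the groups compared has fewer samples; for the other settings the cause was not tested.

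By the labels, mice of different arms share only a number. Deviations of same-numbered tumours of the 2 arms correlated with r of 0.47, 0.12, 0.57 and 0.03, and the own number was the best partner for 3 of 4. Limma-voom with the mouse as a random block (consensus correlation 0.177) gave 0 genes for exercise in non-tumour liver, 4 in tumours, 3437 for the diet, and 6048 and 5640 for tumours of non-exercised and exercised mice. With a fixed block, the number for diet and exercise and the mouse for tumours, the counts were 0, 0, 4069, 5108 and 4729. In the fixed block Usp2 and Mbd1 had an adjusted p of 0.642 each, and Cry2, Tef and Cd300lg in tumours 0.284, 0.353 and 0.326; Usp2 (0.166) and Mbd1 (0.109) also lost their call with the random block, and Bmal1 gained one with the diet (0.000938) in the fixed block. The clock list lost its call for exercise with the fixed block and an estimated correlation together (0.287 and 0.273). For tumours, the fixed block added calls of lists not described otherwise: glucose metabolism in non-exercised mice (0.0306), senescence-associated secretion in exercised mice (0.00675), and immediate early (0.0384 and 0.0146) and female-biased genes (0.0461 and 0.028) in each arm. Of the genes and lists named for tumours and the interaction, blocks changed no call other than these and those given beside the results. The fixed block turned the direction of 2 lists without a call, vascular endothelial markers with the diet (adjusted p = 0.979, and 0.989 with an estimated correlation) and the glucocorticoid response in tumours of non-exercised mice (0.807, and 0.839 with an estimated correlation).

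Of the alternatives computed for named genes, 971 of 990 kept direction and side of the threshold for the diet (17 lost and 2 gained a call). This held for 508 of 544 for exercise in non-tumour liver (16 lost, 20 gained) and 525 of 593 in tumours (30 lost, 29 gained, 9 turned direction). It held for 860 of 884 for tumours of non-exercised mice (11 lost, 6 gained, 7 turned), 850 of 900 of exercised mice (35 lost, 2 gained, 13 turned) and 434 of 467 for the interaction (33 turned). All turns were of values that had not passed, and their cause was not tested. For exercise in tumours, E2f1 was at 0 with upper-quartile factors, at -0.02 without both tumour pieces 3 and between -0.07 and 0.09 with each library left out. Lcn2 lay between -0.07 and 0.64 and Alb between -0.02 and 0.34. For tumours of non-exercised mice, Per1 was at -0.09 without both pieces 3 and between -0.17 and 0.15 with each library left out, and Per3 between -0.34 and 0.13. For tumours of exercised mice each library left out gave E2f1 -0.07 to 0.04, Myc -0.02 to 0.55, Cry1 -0.49 to 0.10, Per1 -0.03 to 0.33, Per3 -0.50 to 0.07, Nr1d1 -0.01 to 0.33 and Dbp -1.03 to 0.31, and without exercised non-tumour pieces 1 and 2 Per3 was at 0.06 and Dbp at 0.42. For the interaction the ranges were Myc -0.54 to 0.09, Per1 -0.05 to 0.32, Per2 -0.26 to 0.12, Per3 -0.40 to 0.21, Dbp -0.33 to 0.99, Bmal1 (Arntl) -0.24 to 0.38, Mki67 -0.82 to 0.31 and Top2a -0.69 to 0.15. Without both tumour pieces 3, Myc was at 0.07, Per3 at 0.05 and Bmal1 (Arntl) at -0.13. Without exercised non-tumour pieces 1 and 2, Myc was at 0.26, Per2 at 0, Per3 at 0.16, Bmal1 (Arntl) at -0.35, Mki67 at 0.24, Top2a at 0.01 and Pcna at 0.04, and with the voom block Per3 was at 0.

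Of 186 list results, 68 kept their side of the threshold with an estimated correlation and 118 lost their call. With RLE factors 181 kept it, 3 lost and 2 gained a call, with the fixed block 166 kept it, 8 lost and 10 gained one, and with the block and an estimated correlation 64 kept it and 120 lost it. With each library left out, adjusted p ran from 4.17e-08 to 0.746 for G2 and M genes and from 0.239 to 0.864 for Myc targets with exercise in non-tumour liver. For Myc targets they ran from 0.391 to 0.811 with exercise in tumours and from 0.125 to 0.982 in the interaction. The r of diet and exercise effects, -0.56, was -0.341 with the shared libraries divided and -0.559 with RLE factors. RLE factors left the r of 0.914 (tumour) and 0.489 (exercise) unchanged. With 4 libraries per group, changes under 2-fold and genes near 1 CPM were often not detectable. Some larger exercise effects, 2.38 (Dbp) and 3.12 (Zbtb16) in non-tumour liver, did not pass either. A gene without a call is not shown to be unchanged.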

Other observations

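The test of the direction shared by diet and tumour was chosen after the result was seen; the gene and list tests were planned.

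Lipid droplet genes were lower in tumours of non-exercised mice: of 15 members 2 rose and 9 fell (2 and 10 over the list alone, camera p = 0.0256, estimated-correlation p = 0.585). In exercised mice 3 rose and 2 fell, as over the list alone (camera p = 0.5, estimated-correlation p = 0.835). Beta-catenin targets, many of which are pericentral hepatocyte genes, had 2 higher and 4 lower of 16 in non-exercised mice (2 and 7 over the list alone, camera p = 0.0225, estimated-correlation p = 0.722). The exercised arm had 1 higher and 8 lower (2 and 10 over the list alone, camera p = 0.00443, estimated-correlation p = 0.679).

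Tumours also differed in markers of epithelium and vessels. Cdh17, a cadherin of intestinal epithelium, rose in tumours of non-exercised mice, where it was at 2.88 to 28.3 CPM, against 0 CPM in 3 and 0.054 CPM in 1 of the 4 non-tumour libraries. Of 12 cholangiocyte and progenitor markers 5 rose and 1 fell in non-exercised mice, as over the list alone (camera p = 0.0829, estimated-correlation p = 0.722, and camera adjusted p = 0.0461 with the mouse as a fixed block). Exercised mice had 5 higher and 0 lower in tumours (6 and 0 over the list alone, camera p = 0.0386, estimated-correlation p = 0.679). Of 11 vascular endothelial markers 3 rose and 1 fell in non-exercised mice, as over the list alone (camera p = 0.366, estimated-correlation p = 0.722). Exercised mice had 5 higher and 0 lower in tumours (5 and 1 over the list alone, camera p = 0.0386, estimated-correlation p = 0.586, a call lost with that block, 0.0561). On the high-fat diet 7 of 15 genes of senescence-associated secretion rose and none fell in non-tumour liver (10 over the list alone, camera p = 9.43e-05, estimated-correlation p = 0.416).

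One hypothesis is that the high-fat diet moves genes of non-tumour liver in the direction of the tumours. The diet effect and the tumour effect of exercised mice, which share no library, had a Pearson r of 0.363 across 14428 genes, which are not independent replicates. Of the genes called in both, 553 were higher in both (376.4 for independent lists) and 457 lower in both (273.9). Opposite directions were found for 105 genes higher with the diet and lower in tumours (323.4) and 182 of the reverse kind (318.8). This fits the hypothesis, but the diet cannot be told apart from tumours in the high-fat livers or from the unlabelled sampling day.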
